A study of Mus musculus with 6 samples.

How the data were processed

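Gene expression was measured by RNA sequencing in pachytene cells purified by STA-PUT from mouse testis at about postnatal day 80. The labels give 3 groups, WT, MAPS KO and MAPS EE;MAPS KO (EE_KO), with 2 libraries each; 3 mice of identical genotype per group were used for purification, over 2 independent experiments. Libraries were made from 1.3 µg of total RNA with a SMARTer kit. The labels pair no libraries across groups and do not say whether a library pools mice or what the letters EE stand for.

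The values are FPKM, per the file headers, with 54532 Ensembl genes in each library. The processing notes name GRCm38 and mm10; the aligner, the counter, the annotation release and the strand of the reads are not given in the sources used here. Gene symbols, types, positions and lengths came from GENCODE M21, which holds 54495 of the genes and lacks 37. The deposited FPKM times the exon-union length of a gene came out as a whole number of reads for 96.8 to 97.0% of values above 0 (tolerance 0.01), and 970 genes were not whole in at least 1 library. The library size that the FPKM imply followed median-of-ratios factors to within 0.0531% rather than the total of reads on genes. Median-of-ratios scaling is therefore close to the deposited scale and adds little as an alternative. The recovered reads gave 14178384 to 16565245 reads on genes per library, so that 1 read over 2 kb stands for 0.0278 to 0.0357 FPKM.

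Genes with a mean FPKM of at least 1 over the 6 libraries were tested, 15368 in all; 533 short RNA genes and 6 lower entries of a repeated symbol were left out. All 6 libraries entered 1 linear model in limma 3.58.1 (R 4.3.3) on log2(FPKM + 1) with a mean-variance trend, without a replicate block. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The added 1 FPKM shrinks log2 changes of genes near 0. A gene near 0 in WT and EE_KO passes the filter only through KO, which favours a rise in KO against WT and a fall in EE_KO against KO. The comparisons were KO against WT, EE_KO against WT and EE_KO against KO.

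The shift of the X and Y chromosomes is the median log2 change of their genes minus that of the autosomal genes, tested with limma's camera (preset inter-gene correlation of 0.01) and adjusted over 6 tests. The 23 gene lists were tested with camera and adjusted over 69 tests; each list's genes were also adjusted over the list alone. The lists were MSCI-silenced X genes, Y genes, X genes of round spermatids, autosomal retrogene copies of X genes, synaptonemal complex and cohesin, meiotic recombination, DNA damage response of the sex body, leptotene and zygotene, mid to late pachytene, meiotic divisions, pachytene piRNA pathway, round and elongating spermatids, spermatogonia, Sertoli cells, Leydig cells, peritubular, endothelial and blood cells, macrophages and other leukocytes, apoptosis with p53 and checkpoint, stress and immediate early genes, mitochondrially encoded transcripts, ribosomal proteins, retroelement and germline defence, and glycolysis of germ cells. Some lists share genes. The groups, comparisons, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined.

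Genes named are the MAPS gene in every library; the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap, passing over clone names and short RNAs; up to 3 members with the smallest p of each list that passed or held a called gene; and the 5 X-linked and 3 Y-linked genes with the smallest p. List members that moved against their list were named after their values were seen. Ratios of X-linked to autosomal FPKM were computed per library. The correlation and covariance of changes between comparisons were set against 20 simulated sets of unchanged groups that share libraries, and the return of KO changes in EE_KO against a later fit that split the shared libraries between the comparisons. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

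The pipeline was tested on simulated data with known changes. For KO against WT it recovered 68.0% of 2-fold rises, 59.2% of halvings, 100% of 4-fold rises and 98.0% of 4-fold falls, with 13 false calls among 14172 unchanged genes. The simulation changed few genes around the WT means, gave all genes the same fixed spread and scaled each library by its true size. It therefore did not test the scaling, or false calls where most genes change, as in the KO data. Nor did it test recovery where still fewer genes change, as in EE_KO against WT. Alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, TPM, median-of-ratios and quantile scaling, models of only the groups compared, a replicate block, no trend, short RNAs kept, repeated symbols summed, a fold limit, an adjusted p below 0.1, camera with an estimated correlation, and each library left out in turn. Added later were limma's voom on the recovered reads, autosomal genes matched on expression (10 nearest per sex-linked gene), protein-coding genes only, and a run without somatic and spermatogonial list genes. Tests meant for deposited counts did not apply, since FPKM were deposited. With 2 libraries per group, no test of other splits of the libraries was made.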

Results

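RNA from STA-PUT purified pachytene cells was compared between WT, MAPS KO (KO) and MAPS EE;MAPS KO (EE_KO, labelled as MAPS overexpression in the KO background) mice, with n = 2 libraries per group. Levels are mean FPKM ± SD of 2 libraries, log2 changes carry limma's standard error (SE), and adjusted p is limma's after the Benjamini-Hochberg method unless camera is named. These p-values measure only the spread between these samples.

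The gene that encodes MAPS, 1700102P08Rik (ENSMUSG00000032611, chromosome 9, 108392805 to 108410934, plus strand), stood at 157.0 and 150.2 FPKM in the WT libraries. It stood at 7.97 and 10.1 in the KO libraries and at 108.6 and 82.2 in the EE_KO libraries. The KO mean was 5.88% of WT (9.04 ± 1.51 against 154 ± 4.82), a log2 change of -3.95 (SE 0.16, adjusted p = 2.75e-07). EE_KO stood at 95.4 ± 18.7, or 62.1% of WT, 3.26 above KO on the log2 scale (SE 0.16, adjusted p = 7.57e-07). Its difference from WT, -0.70, was not called (SE 0.16, adjusted p = 0.254). The mid to late pachytene list had medians of -3.48 in KO against WT and 3.38 in EE_KO against KO. The fall and return of 1700102P08Rik alone therefore cannot be told apart from those of pachytene RNA in general. Ccdc36, a gene on the minus strand that overlaps the 1700102P08Rik locus and was chosen after its values were seen, read 15.5 ± 2.10 FPKM in WT, 3.62 ± 1.30 in KO and 14.3 ± 2.17 in EE_KO (KO against WT -1.86, SE 0.21, adjusted p = 6.17e-05). The deleted part of the gene is not given in the sources used here, nor is the strand of the reads, so the reads left over the locus in KO could not be placed within it.

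**Figure D1:**
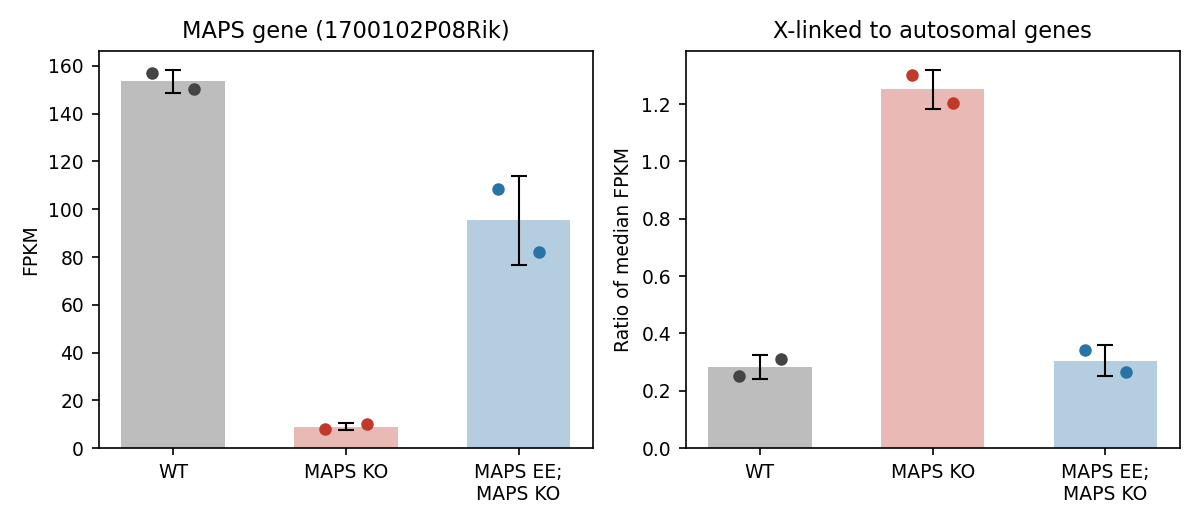
MAPS and the X chromosome in each library. Left, FPKM of the gene that encodes MAPS. Right, ratio of the median FPKM of X-linked to autosomal tested genes. Each point is 1 library, n = 2 per group.

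In KO against WT, transcripts of the X chromosome rose, and those of pachytene cells and spermatids fell. Among X-linked genes that pachytene cells silence, Rpl10 rose from 3.86 ± 0.142 to 53.1 ± 0.147 FPKM, Taf7l from 5.32 ± 0.636 to 37.6 ± 1.62 and Scml2 from 1.71 ± 0.113 to 14.9 ± 0.116. Prm1, which packs sperm chromatin, fell from 472 ± 281 to 1.54 ± 0.667 and Piwil1, of the pachytene piRNA pathway, from 301 ± 0.0924 to 7.87 ± 1.86. Markers of somatic cells rose as well: Star of Leydig cells went from 5.65 ± 0.621 to 83.9 ± 7.20 and Gata4 of Sertoli cells from 4.39 ± 0.0191 to 48.6 ± 8.24. Of 15368 genes tested, 13241 (86.2%) changed, 5842 up and 7399 down (2099 and 3209 of them by 4-fold or more), with 13329 at an unadjusted p under 0.05. Which direction held more genes depended on the scale: 6827 rose and 6408 fell with TPM, 6664 and 6407 with quantile normalization, and 6037 and 7236 with median-of-ratios scaling.

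The median log2 change of the 537 X-linked genes lay 2.29 above that of the autosomal genes, whose own median was -0.34. This shift was 0.20 without a filter, 3.35 with a pseudocount of 0.1, 3.51 with voom and 3.59 with at least 5 FPKM. On the X chromosome 395 genes rose and 115 fell (camera adjusted p = 7.17e-12, adjusted p = 0.373 with an estimated correlation). The median FPKM of X-linked over autosomal genes was 0.252 and 0.312 in the WT libraries and 1.30 and 1.20 in the KO libraries. With 2 libraries against 2 the smallest exact two-sided p is 0.333. X-linked genes held 0.614 ± 0.126% of all FPKM in WT and 4.05 ± 0.0199% in KO. The medians of the autosomes ranged from -0.67 (chromosome 14) to 0.01 (chromosome 18). Beside the X chromosome, 62 markers of Sertoli, Leydig, peritubular, endothelial and blood cells and leukocytes had a mean log2(FPKM + 1) of 2.43 and 2.55 in WT and of 5.53 and 5.35 in KO.

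Of 36 X-linked genes known to be silenced by MSCI, 35 rose and 1, Fthl17a (-2.42), fell. The median was 2.45 (camera adjusted p = 3.05e-09, adjusted p = 0.567 with an estimated correlation). Rpl10 rose by 3.48 (SE 0.15, adjusted p = 4.00e-07), Taf7l by 2.61 (SE 0.13, adjusted p = 6.05e-07) and Scml2 by 2.55 (SE 0.14, adjusted p = 1.10e-06) on the log2 scale. The X-linked genes with the smallest p were Gm648 (4.01, SE 0.17), 1700018G05Rik (3.99, SE 0.17), Lonrf3 (3.68, SE 0.16), Ndufb11 (3.13, SE 0.14, overlapping Rbm10) and Rpl10. X-linked genes of round spermatids moved the other way: 14 of 15 fell and 1700013H16Rik rose by 1.16, with a median of -2.69 (camera adjusted p = 0.00356, adjusted p = 0.658 with an estimated correlation; 0.0943 with at least 5 FPKM). Akap4 of the sperm tail fell from 110 ± 43.0 to 0.540 ± 0.199 FPKM, Cypt2 from 14.3 ± 2.69 to 0.281 ± 0.280 and Tsga8 from 79.9 ± 26.5 to 7.16 ± 0.466. Sertoli and Leydig markers, given below, rose beside these X-linked genes.

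The 6 Y-linked genes of the Y list rose, with a median of 1.49 (camera adjusted p = 0.0133, adjusted p = 0.567 with an estimated correlation). Ddx3y rose by 2.88 (SE 0.16, adjusted p = 1.44e-06), Uba1y by 1.78 (SE 0.19, adjusted p = 4.26e-05) and Eif2s3y by 1.73 (SE 0.14, adjusted p = 7.26e-06), while Gm20827 fell by 2.002 (SE 0.18, adjusted p = 1.43e-05). Over all 12 Y-linked genes tested, 8 rose and 2 fell, and the shift of 1.47 against autosomal genes did not pass (camera adjusted p = 0.0830). Other gene sets passed: -0.07 without a filter (adjusted p = 0.0411), 2.38 with at least 5 FPKM (adjusted p = 0.0245) and 1.30 for protein-coding genes (adjusted p = 0.0181). Autosomal retrogene copies of X-linked genes, which stand in for them during MSCI, fell in 11 of 13 (median -1.88, camera adjusted p = 0.00544, adjusted p = 0.567 with an estimated correlation). Pgk2 fell from 211 ± 4.09 to 5.81 ± 0.950 FPKM, Pdha2 from 96.5 ± 6.07 to 6.88 ± 0.622 and Rpl10l from 273 ± 1.59 to 27.7 ± 2.26; Rbmxl1 alone in this list rose, by 0.40.

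**Figure D2:**
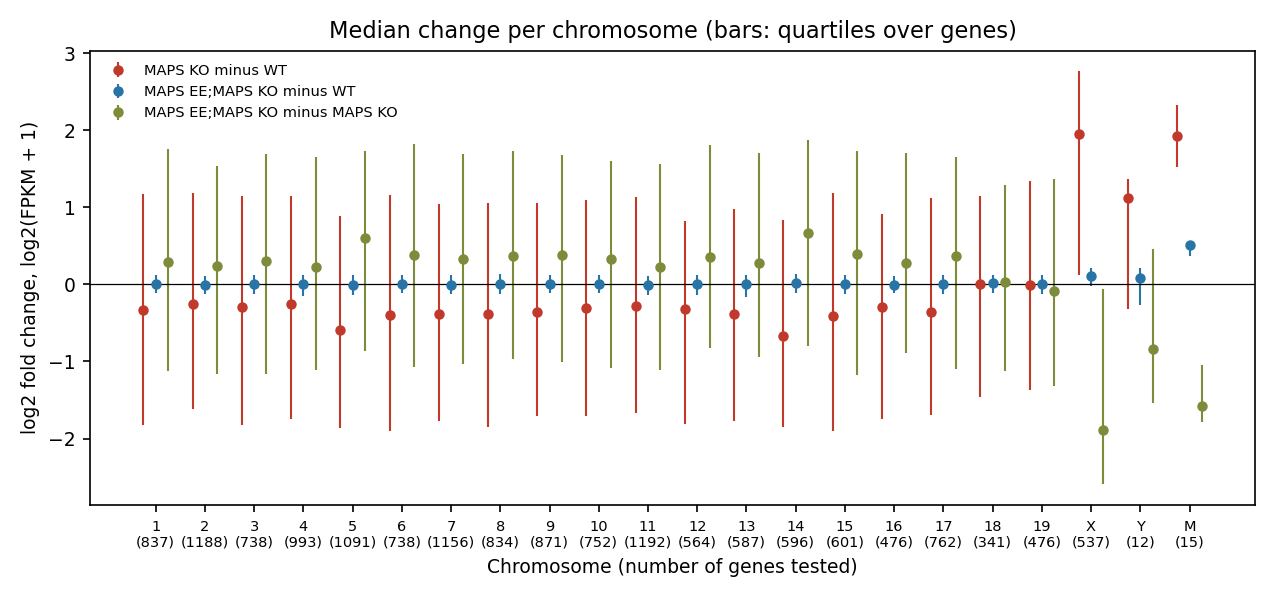
Change of each chromosome in the 3 comparisons, as the median and quartiles of log2 change over the genes tested.

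All 33 mid to late pachytene genes fell (median -3.48, camera adjusted p = 4.98e-08, adjusted p = 0.567 with an estimated correlation). Among them were Meig1 (-5.02, SE 0.10), Nme5 (-4.97, SE 0.11) and Spink2 (-4.79, SE 0.12). All 44 genes of round and elongating spermatids fell (median -4.85, camera adjusted p = 2.24e-10, adjusted p = 0.567 with an estimated correlation). Zpbp2 stood at -5.71 (SE 0.13), Tekt1 at -5.16 (SE 0.11) and Dnajb3 at -4.98 (SE 0.10). Of 24 piRNA pathway genes 20 fell (median -2.04, camera adjusted p = 0.00125, adjusted p = 0.567 with an estimated correlation). Tdrd6 fell by 5.59, Piwil1 by 5.10 and Gtsf1 by 4.09 on the log2 scale, while Fkbp6 (1.58), Btbd18 (1.36) and Pnldc1 (0.67) rose. Of 30 genes of the meiotic divisions 26 fell (median -1.78, camera adjusted p = 0.000184, adjusted p = 0.583 with an estimated correlation). They included Aurkc (-4.09, SE 0.14), Aurka (-3.55, SE 0.14) and Ccnb2 (-3.06, SE 0.12), while Ccnb3 rose by 2.76. The largest falls were those of Prm1 (-7.42, SE 0.41), Prm2 (-7.38, SE 0.34), Tnp2 (-7.19, SE 0.35), Tnp1 (-7.17, SE 0.34), Smcp (-6.50, SE 0.28), Spz1 (-6.24, SE 0.26), Hils1 (-6.20, SE 0.26) and Lkaaear1 (-6.15, SE 0.19), most of them products of spermatid chromatin or sperm tails.

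Lists of earlier meiosis split. Of 17 synaptonemal complex and cohesin genes 8 fell and 4 rose (median -0.34, camera adjusted p = 0.453). Syce1 stood at -3.70 (SE 0.13), Stag3 at -2.85 (SE 0.14) and Meikin at -2.45 (SE 0.14). Of 28 recombination genes 13 fell and 7 rose (median -0.45, camera adjusted p = 0.599). Iho1 and Shoc1 were named in this list but matched no gene symbol, so they were not counted. Prr19 stood at -4.12 (SE 0.12), Psmc3ip at -3.50 (SE 0.13) and Cntd1 at -3.14 (SE 0.12). Of 38 genes of the DNA damage response of the sex body 17 fell and 10 rose (median -0.22, camera adjusted p = 0.651). Mael stood at -3.89 (SE 0.13) and Zfp541 at -3.40 (SE 0.11). Leptotene and zygotene genes rose in 11 of 26 and fell in 11 (median -0.15, camera adjusted p = 0.834). Ccdc155 stood at -3.10 (SE 0.14) and Stra8, which opens meiosis, at 2.996 (SE 0.16). The medians of the synaptonemal complex, sex body, and leptotene and zygotene lists turned positive with TPM (0.04, 0.15 and 0.28) and quantile normalization (0.09, 0.14 and 0.28). They stayed negative with median-of-ratios scaling, which is close to the deposited scale.

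Spermatogonial genes rose in 17 of 19 (median 1.98, camera adjusted p = 0.000171, adjusted p = 0.567 with an estimated correlation). Uchl1 went from 11.8 ± 0.243 to 121 ± 25.2 FPKM and Stra8 from 1.62 ± 0.0993 to 19.99 ± 3.34. Dmrtb1 fell from 480 ± 45.4 to 20.1 ± 3.49 and Id4 fell by 0.42. All 30 Sertoli genes rose (median 3.53, camera adjusted p = 3.67e-09, adjusted p = 0.567 with an estimated correlation). They included Mro (3.56, SE 0.23), Kitl (3.24, SE 0.18) and Gata4 (3.19, SE 0.19). All 16 Leydig genes rose (median 3.74, camera adjusted p = 4.04e-06, adjusted p = 0.567 with an estimated correlation). Akr1cl stood at 4.52 (SE 0.27), Cyp11a1 at 4.23 (SE 0.24) and Star at 3.68 (SE 0.20). The 4 peritubular, endothelial and blood genes rose (median 2.02, camera adjusted p = 0.0408, adjusted p = 0.567 with an estimated correlation; 0.0529 without WT replicate 2, 0.0621 with TPM and 0.0609 with quantile normalization). Acta2 rose by 2.65, Pdgfra by 2.43 and Cdh5 by 1.62. Most of this list, such as Col1a1, Pecam1 and Vwf, was too low to test. The 4 genes stood at a median of 1.07 and 0.784 FPKM in the WT libraries and 7.67 and 6.84 in the KO libraries. Passing the filter thus rested largely on KO, which favours a rise. Macrophage and other leukocyte genes rose in 10 of 12 (median 2.01, camera adjusted p = 0.00713, adjusted p = 0.567 with an estimated correlation). Ccl2 rose by 2.41 and Cd14 by 2.28, while Aif1 fell from 35.3 ± 14.8 to 0.462 ± 0.0371 FPKM. The same limit holds here, with a list median of 0.597 and 0.842 FPKM in the WT libraries and 4.27 and 3.64 in the KO libraries. The largest rises were those of Igfbp3 (5.75, SE 0.23), Klk1b27 (5.72, SE 0.65), Klk1b24 (5.50, SE 0.48), Hsd3b6 (5.37, SE 0.38), Klk1b21 (5.35, SE 0.60), Lrg1 (5.26, SE 0.32), the X-linked Timp1 (5.17, SE 0.32) and Fos (5.02, SE 0.37). Reads of the near-identical Klk1b genes are not safely assigned to 1 of them.

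Genes of apoptosis and the p53 response rose in 22 of 26 (median 2.20, camera adjusted p = 9.50e-05, adjusted p = 0.567 with an estimated correlation). Phlda3 stood at 4.33 (SE 0.22), the cell cycle inhibitor Cdkn1a at 3.22 (SE 0.16) and Sesn2 at 2.997 (SE 0.14). Stress and immediate early genes rose in 21 of 26 (median 3.22, camera adjusted p = 0.000147, adjusted p = 0.567 with an estimated correlation). Ier3 rose by 4.14 (SE 0.19) and Jund by 3.74 (SE 0.18), while the heat shock gene Dnajb1 fell by 2.19 (SE 0.11). Mitochondrially encoded transcripts rose in 11 of 13 (median 1.92, camera adjusted p = 0.00135, adjusted p = 0.567 with an estimated correlation), with mt-Nd3 at 3.16 (SE 0.25), mt-Atp6 at 2.43 (SE 0.18) and mt-Nd6 at 2.35 (SE 0.13). Glycolysis genes of germ cells had a median of -3.63, with 15 of 23 down and 6 up (camera adjusted p = 0.0517; 0.0498 without WT replicate 1, 0.0401 without KO replicate 1 and 0.0356 without KO replicate 2). Ldhc fell by 5.44 (SE 0.16) and Slc2a3 by 4.79 (SE 0.13). Retroelement defence genes had a median of -0.55, with 8 of 13 down and 4 up (camera adjusted p = 0.657), Uhrf1 at -2.29 (SE 0.11) and Dnmt3c at 2.45 (SE 0.17). Ribosomal protein genes had a median of 0.01, with 16 of 47 up and 13 down (camera adjusted p = 0.453), Rps2 at 1.23 (SE 0.11), Rpl14 at 1.22 (SE 0.11) and Rps7 at -1.25 (SE 0.11). The median passed at 0.45 with TPM and 0.66 with quantile normalization. Sertoli and Leydig markers rose beside the apoptosis, stress and mitochondrial genes.

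Adjusted over the list alone, the counts of KO against WT were the same in 20 of 23 lists. They were 10 up and 16 down for the sex body, 15 and 12 for ribosomal proteins, and 6 and 16 for glycolysis. Groups did not overlap for 93.4% of genes, where chance gives 33.3%. The median of all genes in this comparison was -0.29 as deposited and 0.09 with TPM, 0.03 with quantile normalization and -0.22 with median-of-ratios scaling, so small changes depend on the scale.

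**Figure D3:**
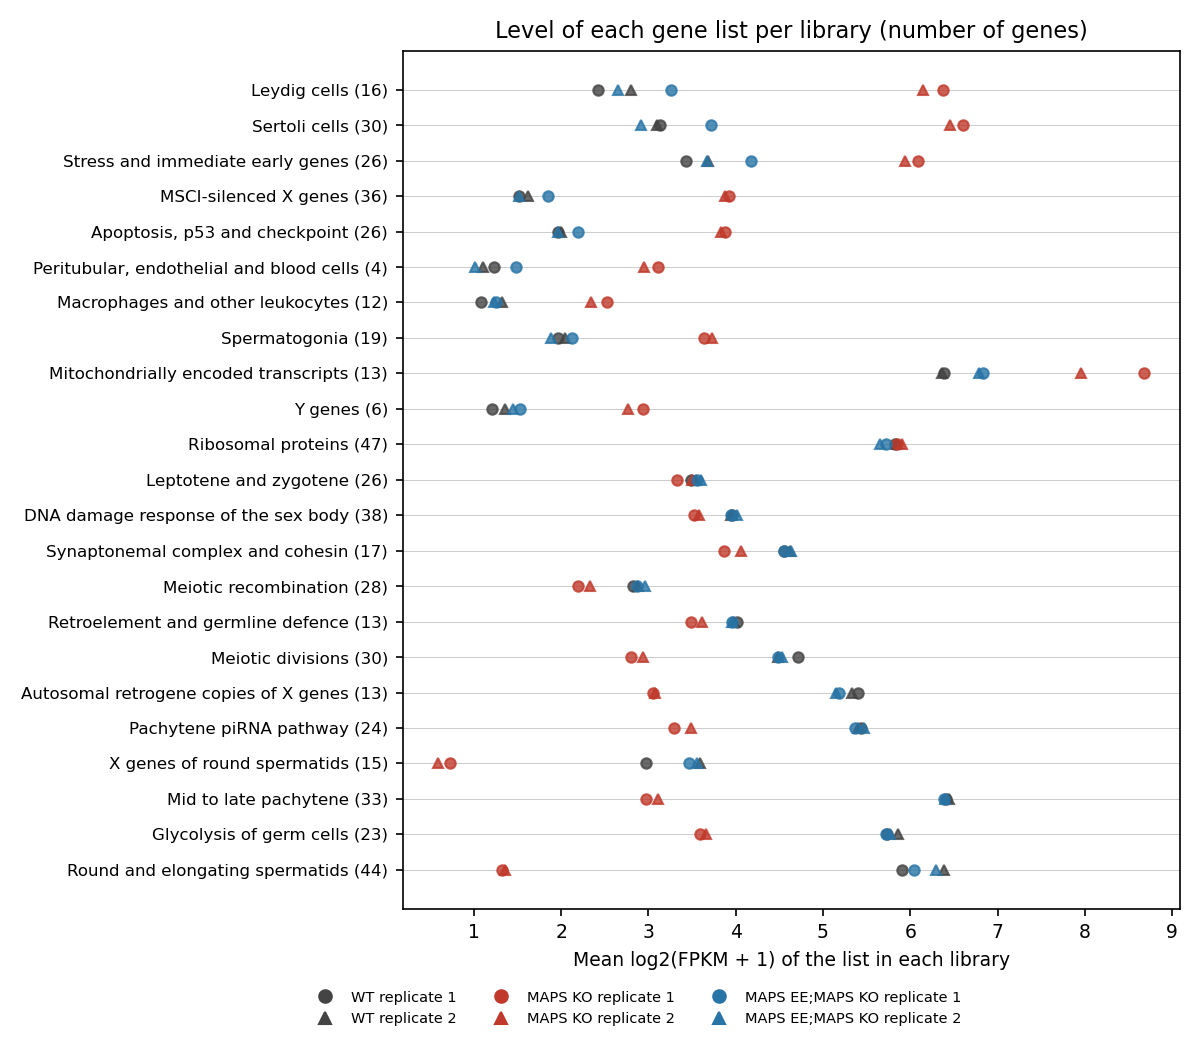
Level of each fixed gene list in each library, as the mean of log2(FPKM + 1) over its tested genes. The number of genes stands beside each list, n = 2 libraries per group.

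EE_KO lay close to WT in most genes. Zfp990, a zinc finger gene on chromosome 4, rose from 0.206 ± 0.00251 to 5.20 ± 0.272 FPKM and stood at 0.227 ± 0.0283 in KO. Tomm7, of the mitochondrial import pore, fell from 40.1 ± 1.35 to 17.9 ± 0.616 (KO 9.66 ± 0.0555), and Parvg from 15.3 ± 0.453 to 4.59 ± 0.547 (KO 0.0829 ± 0.0408). Ldhc, Prm1, Rpl10 and Star stayed uncalled, as did the X-linked genes. Of 15368 genes 7 were called, 4 up and 3 down, and 1150 had an unadjusted p under 0.05; 5606 genes (36.5%, against 33.3% by chance) did not overlap between the groups.

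The genes called were Zfp990 (2.36, SE 0.14, adjusted p = 0.00453), Klb (1.55, SE 0.16, adjusted p = 0.0352), the pseudogene Nudc-ps1 (1.13, SE 0.10, adjusted p = 0.0245), Parvg (-1.55, SE 0.15, adjusted p = 0.0245), Abcg8 (-1.33, SE 0.14, adjusted p = 0.0427), Tomm7 (-1.12, SE 0.10, adjusted p = 0.0245) and the pseudogene Gm4864, named after its values were seen (2.11, SE 0.15, adjusted p = 0.00890). Without 1 library the count was 1 (without WT replicate 1), 1 (WT replicate 2), 0 (KO replicate 1), 0 (KO replicate 2), 19 (EE_KO replicate 1) and 3 (EE_KO replicate 2). With a replicate block 2 genes were called, and Klb, Nudc-ps1, Parvg, Abcg8 and Tomm7 lost their calls. Zfp990 was called in 12 of 18 alternatives, Tomm7 in 8 of 19, Nudc-ps1 in 7 of 19, Parvg in 6 of 19, Klb in 6 of 18 and Abcg8 in 4 of 18. In each of these their direction held, from 2.32 to 4.59 for Zfp990 and from -1.16 to -1.002 for Tomm7. Nudc, chosen after its values were seen, stood at 73.0 ± 8.71 FPKM in WT, 62.0 ± 5.05 in EE_KO and 180 ± 8.02 in KO. It was not called in EE_KO against WT (-0.23, SE 0.12, adjusted p = 0.758), but rose in KO, as Nudc-ps1 did. Whether reads over the pseudogenes came from their parent genes was not tested. On simulated data limma recovered 68.0% of 2-fold rises and 62.5% of halvings in this comparison, and smaller changes were not simulated. The simulated 2-fold rises alone numbered 50, against 7 genes called here. More true changes ease the Benjamini-Hochberg adjustment, so these rates do not give the recovery in the data, and 2-fold changes may have been missed.

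No X-linked gene was called by limma in EE_KO against WT. The X-linked median lay 0.10 above the autosomal one (camera adjusted p = 8.50e-05, adjusted p = 0.559 with an estimated correlation); it was -0.03 without EE_KO replicate 1, 0.03 without WT replicate 1, 0.16 without WT replicate 2 and 0.24 without EE_KO replicate 2. Without a filter it was 0.02, with quantile normalization 0.05 and with a pseudocount of 0.1 0.16. The ratio of X-linked to autosomal medians was 0.343 and 0.267 in the EE_KO libraries. The Y-linked shift was 0.08 (camera adjusted p = 0.513), -0.04 without WT replicate 1, 0.13 without WT replicate 2 and 0.01 without EE_KO replicate 2. The smallest p on the X chromosome belonged to 4930524N10Rik (0.72, SE 0.16, adjusted p = 0.239), Gm6472 (-0.45, SE 0.10, adjusted p = 0.252), Gm7327 (-0.66, SE 0.18, adjusted p = 0.367), H2al1b (-0.77, SE 0.24, adjusted p = 0.457) and Gm6890 (-0.50, SE 0.16, adjusted p = 0.457). On the Y chromosome it belonged to Zfy1 (0.46, SE 0.19, adjusted p = 0.623), Gm20775 (1.37, SE 0.73, adjusted p = 0.758) and Gm29089 (-1.36, SE 0.74, adjusted p = 0.766); the last 2 were called without EE_KO replicate 1 (2.77) and without WT replicate 1 (-2.78) respectively. The somatic markers had a mean of 2.97 in EE_KO replicate 1 and 2.39 in replicate 2.

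Of the 23 lists 10 passed with small medians and with 0 genes called by limma in each. Mitochondrially encoded transcripts had a median of 0.51 (camera adjusted p = 2.49e-05, adjusted p = 0.567 with an estimated correlation), with mt-Nd6 at 247 ± 2.79 FPKM in WT and 372 ± 30.9 in EE_KO (0.58, adjusted p = 0.241), mt-Nd3 at 0.74 and mt-Atp6 at 0.51. Ribosomal protein genes had a median of -0.10 (camera adjusted p = 2.49e-05, adjusted p = 0.567 with an estimated correlation). Rps29 stood at 106 ± 7.50 and 61.3 ± 2.46 FPKM (-0.77, adjusted p = 0.144), Rps28 at -0.60 and Rps9 at -0.47. Stress and immediate early genes had a median of 0.36 (camera adjusted p = 5.04e-07, adjusted p = 0.567 with an estimated correlation). Egr1 stood at 0.85, Ier2 at 0.84 and Jund at 0.52. The list's median was 0.22 without WT replicate 1, 0.55 without WT replicate 2, 0.15 without EE_KO replicate 1 and 0.66 without EE_KO replicate 2. Retrogene copies of X-linked genes had a median of -0.17 (camera adjusted p = 0.00683, adjusted p = 0.567 with an estimated correlation; -0.11 and adjusted p = 0.0712 without WT replicate 1). Rpl39l stood at -1.03 (SE 0.20, adjusted p = 0.195), Rnf113a2 at -0.42 and Rbmxl1 at -0.35.

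The other lists that passed lost the call or changed direction without at least 1 library. Leydig genes had a median of 0.32 (camera adjusted p = 0.00154, adjusted p = 0.596 with an estimated correlation; 0.08 without WT replicate 1, 0.03 without EE_KO replicate 1). Hsd3b6 stood at 1.10, Star at 0.61 and Cyp11a1 at 0.59. Sertoli genes had a median of 0.18 (camera adjusted p = 0.00298, adjusted p = 0.721 with an estimated correlation; -0.23 without EE_KO replicate 1, which passed in the opposite direction with adjusted p = 9.24e-05, and 0.14 without WT replicate 2, adjusted p = 0.0529). Drd4 stood at 0.59, Sox9 at 0.43 and Kitl at 0.35. MSCI-silenced X genes had a median of 0.11 (camera adjusted p = 0.00683, adjusted p = 0.707 with an estimated correlation; -0.05 without EE_KO replicate 1, 0.08 without WT replicate 1). Magea4 stood at 0.42, Rpl10 at 0.34 and Fthl17a at -0.33. X-linked genes of round spermatids had a median of 0.21 (camera adjusted p = 0.00558, adjusted p = 0.676 with an estimated correlation; -0.10 without WT replicate 1, 0.17 without EE_KO replicate 2). H2al1m stood at 0.49, Cypt15 at 0.44 and Actrt1 at 0.40. Y genes had a median of 0.20 (camera adjusted p = 0.0364, adjusted p = 0.567 with an estimated correlation; 0.16 without WT replicate 1, 0.15 without EE_KO replicate 1, 0.29 without EE_KO replicate 2). Zfy1 stood at 0.46, Usp9y at 0.25 and Ddx3y at 0.20. Genes of the meiotic divisions had a median of -0.10 (camera adjusted p = 0.0344, adjusted p = 0.752 with an estimated correlation; 0.04 without WT replicate 1, and -0.10 with adjusted p = 0.312 without EE_KO replicate 1). Aurkc stood at -0.74, Nek2 at -0.33 and Cdc20 at -0.27.

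Adjusted over the list alone, the counts of EE_KO against WT were the same in 19 of 23 lists; 1 retrogene copy, 1 gene of the meiotic divisions and 2 ribosomal protein genes were lower and 1 mitochondrial transcript was higher. Spermatid genes, which did not pass (median 0.03), had medians of -0.21 without WT replicate 1, 0.31 without WT replicate 2 and 0.13 without EE_KO replicate 1, each of which passed. Recombination genes, which did not pass (median 0.09), passed without EE_KO replicate 1 (0.06), and apoptosis genes (median 0.08) passed without EE_KO replicate 2 (0.25).

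EE_KO against KO mirrored KO against WT. Prm1 rose from 1.54 ± 0.667 FPKM in KO to 560 ± 185, Piwil1 from 7.87 ± 1.86 to 313 ± 32.1 and Akap4 from 0.540 ± 0.199 to 125 ± 31.6. Rpl10 fell from 53.1 ± 0.147 to 5.19 ± 1.22, Cyp11a1 from 81.5 ± 4.61 to 5.84 ± 2.48 and Uchl1 from 121 ± 25.2 to 11.3 ± 0.818. Of 15368 genes 13155 changed, 7339 up and 5816 down, with 13251 at an unadjusted p under 0.05. With TPM 6388 rose and 6760 fell, with quantile normalization 6276 and 6680, and with median-of-ratios scaling 7180 and 6033. The X-linked median lay below the autosomal one (shift -2.20, 394 down and 115 up, camera adjusted p = 7.17e-12, adjusted p = 0.373 with an estimated correlation), and the Y-linked shift was -1.16 (8 down, 2 up, camera adjusted p = 0.0830). The X-linked shift was -0.21 without a filter, -3.23 with a pseudocount of 0.1, -3.33 with voom and -3.44 with at least 5 FPKM. The Y-linked shift passed at 0.06 without a filter (adjusted p = 0.0411), -2.33 with at least 5 FPKM (adjusted p = 0.0245) and -1.57 for protein-coding genes (adjusted p = 0.0203).

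The largest rises were those of Prm1 (7.77, SE 0.41), Tnp2 (7.33, SE 0.35), Prm2 (7.07, SE 0.34), Smcp (7.03, SE 0.28), Tnp1 (6.48, SE 0.34), Spz1 (6.40, SE 0.26), Hils1 (6.38, SE 0.26) and Odf1 (6.38, SE 0.27). The largest falls were those of Igfbp3 (-5.05, SE 0.23), Klk1b21 (-4.90, SE 0.60), Timp1 (-4.88, SE 0.32), Klk1b27 (-4.79, SE 0.65), the lipid carriers Apoe (-4.49, SE 0.24) and Apoc1 (-4.43, SE 0.31), Klk1b24 (-4.43, SE 0.48) and Ass1 (-4.42, SE 0.27). On the X chromosome the smallest p belonged to 1700018G05Rik (-4.22, SE 0.17), Gm9059 (3.64, SE 0.16, listed at 0 in KO), Ndufb11 (-3.18, SE 0.14), Akap4 (6.33, SE 0.27) and Ctag2 (3.63, SE 0.16). On the Y chromosome it belonged to Ddx3y (-2.68, SE 0.16), Eif2s3y (-1.76, SE 0.14) and Gm20827 (1.73, SE 0.18).

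MSCI-silenced X genes fell in 35 of 36 (median -2.34, camera adjusted p = 3.05e-09). Rpl10 stood at -3.14, Scml2 at -2.71 and Taf7l at -2.55. The 6 Y genes fell (median -1.24, camera adjusted p = 0.0217). Spermatid genes rose in 44 of 44 (median 4.93, camera adjusted p = 1.81e-10), mid to late pachytene genes in 33 of 33 (median 3.38, camera adjusted p = 3.29e-08), piRNA genes in 20 of 24 (median 2.22, camera adjusted p = 0.000767) and retrogene copies in 12 of 13 (median 1.72, camera adjusted p = 0.00529). Sertoli genes fell in 30 of 30 (median -3.35, camera adjusted p = 3.97e-09), Leydig genes in 16 of 16 (median -3.56, camera adjusted p = 5.09e-06), peritubular, endothelial and blood genes in 4 of 4 (median -1.85, camera adjusted p = 0.0364), leukocyte genes in 10 of 12 (median -1.75, camera adjusted p = 0.00683) and spermatogonial genes in 17 of 19 (median -1.97, camera adjusted p = 0.000166). Apoptosis genes fell in 21 of 26 (median -2.14, camera adjusted p = 0.000136), stress genes in 20 of 26 (median -2.89, camera adjusted p = 0.000274) and mitochondrially encoded transcripts in 11 of 13 (median -1.58, camera adjusted p = 0.00356). Each of these 14 lists had adjusted p = 0.567 with an estimated correlation. X-linked genes of round spermatids rose in 14 of 15 (median 2.57, camera adjusted p = 0.00202, adjusted p = 0.633 with an estimated correlation) and genes of the meiotic divisions in 26 of 30 (median 1.69, camera adjusted p = 0.000184, adjusted p = 0.583 with an estimated correlation).

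Glycolysis genes rose in 16 of 23 and fell in 6 (median 3.46, camera adjusted p = 0.0468, adjusted p = 0.567 with an estimated correlation). Ldhc stood at 5.36 and Slc2a3 at 4.74. Without WT replicate 1 the adjusted p was 0.0646, without WT replicate 2 0.0586, without EE_KO replicate 1 0.0516 and without EE_KO replicate 2 0.0503. The lists that did not pass were those of the synaptonemal complex (median 0.47, camera adjusted p = 0.472), recombination (0.61, 0.472), the sex body (0.29, 0.450), leptotene and zygotene (0.17, 0.954), ribosomal proteins (-0.10, 0.0725) and retroelement defence (0.57, 0.686). Ribosomal protein genes passed without KO replicate 1 (-0.06, adjusted p = 0.0440), and with TPM (-0.50, adjusted p = 0.00140), quantile normalization (-0.73, adjusted p = 7.64e-05) and median-of-ratios scaling (-0.17, adjusted p = 0.0370). Spo11, which makes meiotic breaks, rose by 2.75 (SE 0.14), Syce1 by 3.55 (SE 0.13), Zfp541 by 3.23 (SE 0.11) and Uhrf1 by 2.30 (SE 0.11). Adjusted over the list alone, the counts of EE_KO against KO were the same in 20 of 23 lists. They were 16 up and 6 down for the sex body, 7 and 20 for ribosomal proteins, and 8 and 4 for retroelement defence.

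Of the 13241 genes changed in KO against WT, 12757 (96.3%) changed in the opposite direction in EE_KO against KO and 3 in the same direction. Among them 5623 rose in KO and fell in EE_KO, where independence gives 2211, and 7134 fell in KO and rose in EE_KO, where independence gives 3533. The comparisons share the KO libraries: over 20 simulated sets of unchanged groups the correlation of log2 changes across genes was -0.50 and the covariance -0.0232, against -0.99 and -4.10 in the data. With KO replicate 1 set against WT and KO replicate 2 against EE_KO, 11793 genes had opposite calls (93.6% of 12603) and the covariance was -4.08. With the KO replicates the other way round, 11837 did (94.5% of 12525), with a covariance of -4.09. Between KO against WT and EE_KO against WT, which share the WT libraries, the correlation was 0.34 (simulated 0.51) and the covariance 0.174 (simulated 0.0240). With the WT libraries split in the same way, the covariance was 0.137 and 0.160. Of the 7 genes called in EE_KO, 6 were also called in KO, where 86.2% of all genes were: 2 up in each (1.52 under independence), 3 down in each (1.44), and Klb up in EE_KO and down in KO (1.93). The comparisons share the WT libraries.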

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

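The alternatives that used recovered reads, expression-matched or protein-coding genes, or left out somatic and spermatogonial genes were chosen after the result was seen, as was the split of the KO libraries, which gave a return of 11793 and 11837. The count of genes changed stayed within 1.5 times its value in 21 of 22 alternatives for KO against WT and for EE_KO against KO. With at least 5 FPKM it was 7704 and 7655, since only 8767 genes were tested, and the return of KO changes was then 7471. With 1 library left out the counts were 12525 to 13230 and 12373 to 13174, and the return 11991 to 12427. With voom they were 13223 and 13151.

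The 7 genes called in EE_KO against WT became 4 with a pseudocount of 0.5, 0 without a filter, 2 with at least 5 FPKM, 2 with TPM, 0 with only the groups compared, 2 with a replicate block and 0 to 19 with 1 library left out; the cause was not tested. In limma's test 1150 genes had an unadjusted p under 0.05, and voom called 9, of which 6 were shared. Differences of replicate 1 minus replicate 2 correlated between the groups at -0.03, 0.05 and 0.09, and with the block 13225 and 13105 genes changed in KO against WT and EE_KO against KO.

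The X-linked shift kept its direction in KO against WT, from 0.20 without a filter to 3.59, and in EE_KO against KO, from -3.44 to -0.21. With 1 library left out it was 2.23 to 2.37 and -2.33 to -2.07. With an estimated correlation camera gave adjusted p of 0.373, 0.559 and 0.373 in KO against WT, EE_KO against WT and EE_KO against KO. The correlation estimated for X-linked genes was 0.286, where the preset is 0.01, and a higher correlation widens the variance that camera allows for. The shifts of 2.29, 0.10 and -2.20 do not use the correlation and so could not change. In EE_KO against WT the X-linked shift was -0.026 to 0.241 with 1 library left out and turned negative without EE_KO replicate 1. In that library 62 somatic genes were 0.62 higher than in replicate 2. In 2 of 2 groups (WT and EE_KO) the library with more somatic RNA had the higher X to autosome ratio, which may be chance with so few groups. Whether somatic RNA is the cause was not tested.

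The Y-linked shift of KO against WT, 1.47 over 12 genes, was -0.072 without a filter (389 genes, adjusted p = 0.0411), 2.38 with at least 5 FPKM (3 genes, adjusted p = 0.0245) and 1.30 for protein-coding genes (7 genes, adjusted p = 0.0181). In EE_KO against KO it was 0.057, -2.33 and -1.57. These sets hold other genes. Over the same 12 genes the shift of KO against WT was 0.72 against autosomal genes of matched expression, 2.22 with a pseudocount of 0.1 and 2.27 with voom. It did not pass in these. That of EE_KO against KO was -1.80 with voom. The cause was not tested further.

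With an estimated correlation 0, 0 and 0 of 23 lists passed in KO against WT, EE_KO against WT and EE_KO against KO, where 16, 10 and 17 had passed; adjusted p ran from 0.567 to 0.957, 0.994 and 0.988. With 1 library left out 5 to 10 lists passed in EE_KO against WT. Sertoli genes in EE_KO against WT turned from 0.18 to -0.23 without EE_KO replicate 1, passing with adjusted p = 9.24e-05, and were -0.23 to 0.58 with 1 library left out. The 62 somatic genes, which include this list, differ between these replicates as given above; why they differ was not tested. At 14178384 to 16565245 reads per library, the median SD between replicates was 0.17 on the log2 scale for 2730 genes of 1 to 2 FPKM and 0.13 for 5458 genes of 10 to 100 FPKM.

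Besides the estimated correlation and libraries left out, these lists crossed the threshold. X-linked genes of round spermatids lost the call with at least 5 FPKM in KO against WT (adjusted p = 0.0943) and EE_KO against KO (0.0731), and without a filter in EE_KO against WT (0.130). Peritubular, endothelial and blood genes lost it with TPM and quantile normalization in KO against WT (0.0621, 0.0609) and EE_KO against KO (0.0592, 0.0559). Ribosomal protein genes passed with TPM and quantile normalization in KO against WT (0.01005, 0.000212), and in EE_KO against KO with these (0.00140, 7.64e-05), median-of-ratios scaling (0.0370), at least 5 FPKM (0.0176) and a pseudocount of 0.1 (0.0484). Glycolysis genes passed in KO against WT in 7 alternatives (0.00332 to 0.0484) and lost the call in EE_KO against KO in 5 (0.0503 to 0.0613). In EE_KO against WT quantile normalization ended the calls of MSCI-silenced X genes (0.0527), Y genes (0.0640), retrogene copies (0.0536) and meiotic divisions (0.201) and added leptotene and zygotene genes (0.0450). Y genes lost theirs with at least 5 FPKM (0.412) and meiotic divisions without the trend (0.0556), while recombination genes passed with at least 5 FPKM in EE_KO against KO (0.0478). The cause was not tested.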

Other observations

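Of the tests below, that on X-linked germ line genes was set before its result was seen. The other 7, the scan of gene families and types, the check without Nr0b1 and the 3 tests at the end were chosen after. The ± values of these tests are standard errors over genes, not limma's. Genes do not vary independently: the estimated correlation was 0.115 for spermatogonial, 0.286 for X-linked and 0.465 for synaptonemal complex genes. These errors are therefore too small and do not measure the spread between libraries.

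Families set by gene symbol were counted in KO against WT without a test of enrichment; of all 15368 genes 5842 rose and 7399 fell. All 17 ciliary dyneins fell (median -4.16, from -4.22 to -3.65 over the scalings), as did all 30 Cfap genes (-4.03), all 12 tektins and radial spoke genes (-4.56) and all 6 Tssk kinases (-3.90). Rhox genes rose in 5 of 6 and fell in 0 (2.02), and Mage genes rose in 11 of 13 and fell in 2 (1.85). Mage genes low in WT, such as Magea4 (0.220 FPKM in WT, 3.40 in KO), passed the filter through KO, which favours a rise. Klk1b genes rose in 6 of 8 and fell in 1 (3.45). Cholesterol and steroid synthesis genes rose in 13 of 18 and fell in 4 (1.67), and collagens rose in 12 of 21 and fell in 6 (0.84). Histone genes with a Hist symbol rose in 3 of 17 and fell in 10 (-1.04). They include Hist1h1t of the mid to late pachytene list. Beside these rises, 16 of 16 Leydig genes (3.74) and 30 of 30 Sertoli genes (3.53) rose. Proteasome genes (12 up and 13 down of 36, -0.01) turned to 0.42 with TPM, 0.07 with median-of-ratios and 0.55 with quantile scaling, and zinc finger genes (75 up and 102 down of 232, -0.19) to 0.15 with TPM and 0.07 with quantile scaling; the other families kept their direction under these scalings. These are the 12 families scanned.

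Long non-coding RNAs fell in 1428 of 1844 and rose in 247 in KO against WT (median -1.66, from -2.48 to -1.26 over the scalings) and rose in 1409 and fell in 249 in EE_KO against KO. Pseudogenes fell in 602 of 1112 and rose in 234 (median -0.70, from -0.70 to -0.35), unclassified genes fell in 137 of 230 and rose in 62 (-0.94), and protein-coding genes stood at 0.02 (5294 up, 5227 down), and at 0.44 with TPM, 0.33 with quantile and 0.09 with median-of-ratios scaling, with 4 gene types scanned. Since EE_KO lay close to WT, the filter on the mean of 6 libraries passes genes absent from KO more easily than genes found only in KO. Without a filter 9129 of all genes rose and 9778 fell in KO against WT. Gene types were not counted without the filter.

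X-linked genes were higher in KO against WT. Against somatic cells as the only source, 15 X-linked germ line genes lay 2.61 ± 0.453 (SE) above the autosomal median, 14 of them called up. Of these genes 9 are shared with the MSCI list, and the value was 2.52 without Nr0b1. The filter favours this rise, since genes such as Mageb4 (0.191 FPKM in WT, 2.75 in KO) passed it through KO. Among those above 1 FPKM in WT, Dmrtc1a, Nr0b1, Taf7l, Nxf2, Tex11 and Tktl1 rose and Fthl17a fell. Spermatogonial genes lay 2.33 ± 0.494 above the autosomal median, which earlier germ cells that have not yet silenced the X chromosome could give. Clu of Sertoli cells (162 to 2201 FPKM) and Insl3 of Leydig cells (48.9 to 1299 FPKM) show that somatic RNA also rose despite STA-PUT. Failed silencing in pachytene cells stays open: the X-linked shift was 1.99 ± 0.109 against autosomal genes of matched expression, but cells of other stages bring active X chromosomes too. The design ties the mix of cells to the genotype, so these sources cannot be told apart here.

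Pachytene and spermatid genes were lower in KO against WT. Dilution of the same germ cells by other cells would lower each germ cell list alike, yet the synaptonemal complex list lay 3.14 ± 0.563 above the mid to late pachytene list. Leptotene and zygotene genes lay 3.33 ± 0.524 above it, as germ cells of an earlier stage in KO would give. This cannot single out an earlier stage, which stays a hypothesis. The mid to late pachytene list fell so far (median -3.48) that ribosomal protein genes (median 0.01) also lay above it. Leptotene and zygotene genes did not rise as a list (median -0.15, 11 up and 11 down, camera adjusted p = 0.834). That list shares genes with the synaptonemal complex list, and both hold genes of both directions. Loss of later cells and lower expression in cells of the same stage were not separated.

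The genes called in EE_KO against WT were few. A share of KO-like cells in EE_KO would give levels between WT and KO, yet for 3 of 7 (Zfp990, Klb and Gm4864) the EE_KO libraries lay outside the range of the WT and KO libraries. The 4 others would need a share of at least 47.1% (Nudc-ps1), while the 2099 genes raised 4-fold or more in KO reached a median share of 1.86% and a 95th percentile of 6.16% in EE_KO. Against a segment of another strain around the MAPS locus, 0 of 7 lay on chromosome 9. Strain differences elsewhere and an effect of the MAPS EE allele stay open and were not tested.

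Within groups, 62 somatic genes were 0.62 ± 0.0709 (SE) higher in EE_KO replicate 1 than in replicate 2. In 2 of 2 groups (WT and EE_KO) the library with more somatic RNA had the higher X to autosome ratio, which may be chance with so few groups. The KO libraries, not part of this test, had the same order (5.53 with 1.30, 5.35 with 1.20). In WT replicate 2 minus replicate 1, Leydig (0.20) and leukocyte genes (0.22) were higher, but Sertoli (-0.05) and peritubular, endothelial and blood genes (-0.12) were not. Mitochondrial transcripts differed between the KO replicates by 0.86 and somatic genes by 0.18, a difference of 0.69 ± 0.320. Transcripts of the mitochondrial genome held 11.9% and 7.25% of all FPKM in KO, 1.80% and 1.83% in WT and 2.67% and 2.46% in EE_KO. These 3 tests were set up as further patterns and moved here after their results were seen.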
